A study of Mus musculus with 4 samples.

How the data were processed

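The measurements were enhanced crosslinking and immunoprecipitation (eCLIP) of PTBP1, polypyrimidine tract binding protein 1, an RNA-binding protein that regulates splicing. Per the labels, the material was whole heart of wild-type C57BL/6 mice. There were 2 immunoprecipitates (IP) and 2 size-matched inputs, 4 samples in all, and each input was taken from the lysate of its own immunoprecipitate before the antibody step. In eCLIP, RNA is crosslinked to protein with ultraviolet light, trimmed with RNase and recovered with an antibody, and the input shows which RNA is abundant without selection.

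The submitters' processing notes name UMI-tools 0.5.1, cutadapt 2.7 and STAR 2.6.0c, without their roles, and the builds mm10 and hg38. The program that called the clusters, the annotation behind it and the test behind the p-values are not given in the sources used here. The authors deposited 1 table of clusters per replicate, so clusters were called in each replicate separately. Per the file headers, each cluster has a chromosome, start, end, strand, a log2 fold change and a −log10 p-value. The deposited log2 fold is that of the immunoprecipitate over its own size-matched input. The deposited −log10 p-value stops at 400 in both tables and equals 0 for every cluster with a negative log2 fold, so it measures enrichment in 1 direction only. Neither read counts nor library totals were used here, so the depth behind a cluster is unknown, and no interval is given for a single fold. The build was taken as mm10, the same assembly as GRCm38, because the last replicate 1 cluster of chromosome 1 ends at 195161571, beyond the end of that chromosome in the later mouse assembly. Coordinates are printed counting from 1.

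A cluster was called enriched at a log2 fold of at least 3 and a −log10 p of at least 3, thresholds chosen before the data were examined. A cluster of replicate 1 was called reproducible when it was enriched and overlapped an enriched cluster of replicate 2 by at least 1 nt on the same strand. Fisher's exact test (two-sided) compared enriched with not enriched clusters for such an overlap. Shares have 95% Wilson intervals, which treat clusters as independent. Folds of the replicates were compared over each replicate 1 cluster and the replicate 2 cluster that shared most nucleotides with it. The folds given for a gene are those of the overlapping enriched pair with the highest lower-of-2 fold, whose clusters may share as little as 1 nt; pairing by most shared nucleotides was an added alternative. The tables were checked for duplication: 196 clusters had identical coordinates in both, and 0 of them had an identical log2 fold.

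Clusters were placed in genes by their midpoint, with the spans of 34627 protein-coding and lncRNA genes of GRCm38. The gene table used here has neither strand nor exons. A gene's strand was therefore read from clusters lying in that gene alone, where it had at least 3 of these over both tables and at least 90% were on 1 strand, which gave a strand for 12470 genes. In genes with at least 3 such clusters, 0.14% were on the minority strand. In this way 97.7% of the clusters of each replicate were placed in 1 gene. Clusters in several possible genes (2070 in replicate 1 and 2148 in replicate 2) or outside all spans (6467 and 6540) were left out of gene results. The feature types planned before the data were examined need exon annotation, and were replaced by the gene class and by the position within the gene span. Motif content, distance to splice sites and count models of immunoprecipitate against input were planned for the case that sequence, exons and read counts could be used, and were not analysed here.

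There were 20 gene lists, fixed before the data were examined and matched to gene symbols through synonyms. The planned test counted members with a reproducible cluster among members with a cluster in both replicates, against 10000 random lists matched in 10 bins on the number of clusters per gene (two-sided permutation p, Benjamini-Hochberg adjusted over the 20 lists). A further test was chosen after seeing the data: the mean over members of each gene's median log2 fold, against 10000 random lists with the same matching, in each replicate separately. A list was called higher or lower in this test when both replicates had an adjusted p under 0.05 in the same direction. The smallest p these lists can give is 0.0002. Both tests compare genes within 2 lysates, and a p-value over genes or clusters does not measure the spread between animals. Nothing in the labels says that the 2 replicates came from different mice, so the spread between them may be technical.

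The genes named were set by rule before the data were examined. They are the 15 genes with the highest lower-of-2 log2 fold of a reproducible cluster, the 10 genes with most reproducible clusters, up to 4 members per list by the same lower fold, and every member of the list of PTB family genes and known PTBP1 targets with a cluster in both replicates. Predicted genes and mitochondrially encoded genes were left out of the first pair of groups, and ties went by alphabet. Genes named outside this rule are marked where they appear.

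Alternatives set before the data were examined were log2 fold thresholds of 1 and 2, a −log10 p threshold of 5, leaving out mitochondrial, contig and small RNA clusters, overlap of at least 50% of the shorter cluster or of both, overlap regardless of strand, each replicate alone, Fisher's exact test of lists without matching, and matching on covered length. Alternatives added later were the deposited p adjusted by Benjamini-Hochberg, joining touching clusters, the last 2000 nt of the span, and other matching, averaging and span limits for the fold test, pairing by most shared nucleotides, and 2 further marker lists in the cell-type difference. The overlap and list tests were tested on simulated data. All 800 planted pairs among 2000 simulated clusters were found. Of 400 simulated lists of 25 genes among 13000, 3.25% without an effect and 91.2% with 30 percentage points added had p under 0.05 in the count test. In the fold test it was 4.25% without an effect and 99.2% with 1 log2 unit added. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.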

Results

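PTBP1 binding to RNA was measured in whole heart of wild-type mice by eCLIP, in 2 immunoprecipitates and 2 size-matched inputs. The series title concerns PTBP1 in cardiac fibroblasts and alternative splicing, and the comparison of immunoprecipitate with input asks which heart RNAs PTBP1 was crosslinked to. Replicate 1 held 376266 clusters and replicate 2 held 388894, with a median length of 69 nt and 66 nt. Each fold and p-value of a cluster is the authors' own, from the authors' deposited tables, and compares an immunoprecipitate with the input of its own lysate. The number of reads behind a cluster is unknown.

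PTBP1 clusters stood out from input at many sites, and most of these were shared between the lysates. In replicate 1, 23757 clusters (6.31%) were enriched, at a log2 fold and a −log10 p of at least 3, and in replicate 2 there were 18330 (4.71%). An enriched cluster of replicate 2 overlapped 14958 of the replicate 1 clusters, 63.0% of them (95% Wilson interval 62.3 to 63.6). Seen from replicate 2, 14452 clusters or 78.8% (78.2 to 79.4) were shared. Of the clusters that were not enriched, 1.68% in replicate 1 and 3.37% in replicate 2 had such an overlap. The odds ratio was 99.5 (95% interval 95.9 to 103) in replicate 1 and 107 (103 to 111) in replicate 2, and both p-values of Fisher's exact test were smaller than the software can hold. Any cluster of the other replicate, enriched or not, overlapped 99.3% of enriched clusters in replicate 1 and 98.2% in replicate 2. For all clusters it was 56.0% and 54.4%. The odds ratios therefore also reflect whether an overlapping cluster was called at all, not only its enrichment. Of the 13538 genes with clusters in both replicates, 3378 held at least 1 reproducible cluster.

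Across 210643 overlapping cluster pairs, the log2 folds of the lysates had a Pearson correlation of 0.789 (95% interval 0.788 to 0.791) and a Spearman correlation of 0.743. These are correlations across clusters, which are not independent replicates. Over the 28733 pairs enriched in at least 1 replicate, Pearson's r was 0.228, and over the 24911 pairs with a −log10 p of at least 3 in both it was 0.570; choosing pairs by their values narrows the range and lowers a correlation by itself. Over all pairs the folds differed by a median of 0.13 log2 units, replicate 1 higher, with a standard deviation of 1.01. Over pairs enriched in at least 1 replicate, which are chosen by fold, it was 0.47 with a standard deviation of 1.18. A gap of about 1 log2 unit between single sites was therefore within the spread between lysates.

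**Figure D1:**
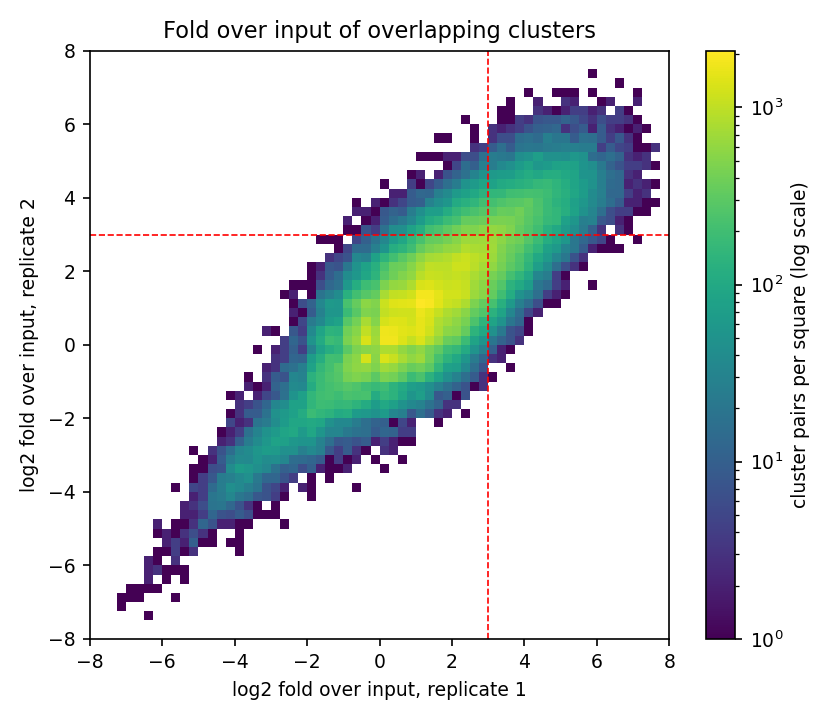
Log2 fold over input of overlapping clusters, replicate 1 on the x axis and replicate 2 on the y axis, coloured by the number of pairs per square on a log scale. Red dashed lines mark the threshold of 3. The 210643 pairs follow a diagonal with a Pearson correlation of 0.789.

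The strongest shared site lay in Sox5, which encodes a transcription factor (Entrez gene 20678). Its cluster on chromosome 6 from 144766142 to 144766456 had a log2 fold of 7.05 in replicate 1 and 6.97 in replicate 2 in the authors' deposited tables, with −log10 p of 48.9 and 46.2. Xdh, the gene of xanthine dehydrogenase (Entrez gene 22436), followed with 6.62 and 6.66 in neighbouring clusters on chromosome 17, from 73903736 to 73903861 in replicate 1 and from 73903603 to 73903736 in replicate 2, which share 1 nt. Next were Frmd4b with log2 folds of 7.24 and 6.59, Unkl with 6.55 and 6.60, and Ebf1, the gene of a transcription factor, with 6.54 and 7.11. The cluster of Epb41l2, a gene of the membrane skeleton, had 7.12 and 6.52. Mtmr1, Tshz2, Auts2, Prrc1, Nxpe4, Ggnbp2, Arhgap10, Vwa5a and Ephb4, the gene of an ephrin receptor, completed the leading 15. The lower of the 2 log2 folds ran from 6.97 in Sox5 to 6.25 in Ephb4, a range smaller than the spread between lysates. Their order is thus not resolved. Of the 95 named genes with a reproducible cluster, 14 had folds from a pair that shared under 10 nt. When each replicate 1 cluster was instead paired with the enriched cluster sharing most nucleotides, a choice made after seeing the data, Sox5 still led and 11 of the 15 stayed among the leading 15. Unkl, Prrc1, Nxpe4 and Ephb4 left, and the lower log2 fold fell most in Unkl, from 6.55 to 5.03. The Sox5 cluster lay 1.68% into the gene span from its 5′ end and the replicate 1 cluster of Xdh 70.1% into it; exons and introns were not used here.

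Single genes carried up to 83 reproducible clusters. Touching clusters were counted separately, so these are not counts of separate sites. Over all genes, joining touching clusters turned the 14958 reproducible clusters into 10084 regions. Gpc6, which encodes a glypican of the cell surface (Entrez gene 23888), held 83 reproducible clusters. Ebf1 held 82, Mecom 67, Zbtb20 62 and Rora 61, and all 4 encode transcription factors. They were followed by Tshz2 with 56, Itpkb, an inositol phosphate kinase gene, with 55, Wwox with 54, Prkg1, the gene of a cGMP-dependent protein kinase, with 52, and the phosphatase gene Ptprg with 49. Genes with many reproducible clusters also had many clusters of any fold: Gpc6 had 664 in replicate 1 and 748 in replicate 2, while Itpkb had 141 and 174. The median gene with any reproducible cluster had 2, and 339 genes had 10 or more.

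PTBP1 sites lay in genes of its own family and in 12 of the 18 genes of the list of PTB family genes and known targets with clusters in both replicates. Ptbp2, the neuronal relative of PTBP1 (Entrez gene 56195), held 10 reproducible clusters, the strongest pair with log2 folds of 6.11 (replicate 1, chromosome 3 from 119745474 to 119745572) and 4.76 (replicate 2, from 119745569 to 119745616), which share 4 nt. Among Ptbp2 clusters paired by most shared nucleotides, the strongest pair shared 146 nt, from 119745169 to 119745314 in replicate 2, with 4.56 and 5.88. Ptbp3 held 5, with 5.20 and 5.01 for the strongest. Among splicing targets, the strongest clusters had log2 folds of 5.04 and 6.04 in Dlg4, which encodes a postsynaptic scaffold, and 5.21 and 4.14 in the GABA receptor gene Gabbr1. The calcium channel gene Cacna1c held 19 reproducible clusters (strongest 5.82 and 4.46), the actin crosslinker gene Actn1 4 (4.16 and 4.51), the death receptor gene Fas 3 (4.39 and 4.52) and Rtn4 3 (4.99 and 4.03). Titin (Ttn) held 3 (4.55 and 3.78), tropomyosin 2 (Tpm2) 2 (4.38 and 3.06) and filamin A (Flna) 1 (3.93 and 3.52). The pairs printed for Cacna1c, Actn1 and Tpm2 shared 2, 9 and 6 nt, so their folds are of neighbouring clusters.

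The other 6 members had no reproducible cluster. The best pair in Tpm1 had log2 folds of 2.74 and 2.82, just under the threshold, with −log10 p of 55.4 and 59.8. In Pkm, the pyruvate kinase gene whose alternative exons PTBP1 is known to regulate, it had 2.62 and 2.43, with −log10 p of 1.35 and 2.13. Src had 2.36 in both, Exoc7 1.54 and 0.49, Fgfr2 0.84 and 0.03, and Bak1 0.84 and −1.77. The Ptbp1 gene itself could not be scored by the rule used here. All 9 clusters per replicate in its span, on chromosome 10 from 79854432 to 79864435, lay where it overlaps the span of Plppr3. All were on the + strand, but the strand of neither gene could be read from clusters. None of these clusters was enriched. The highest log2 fold among them was 2.01 in replicate 1 and 2.74 in replicate 2.

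**Figure D2:**
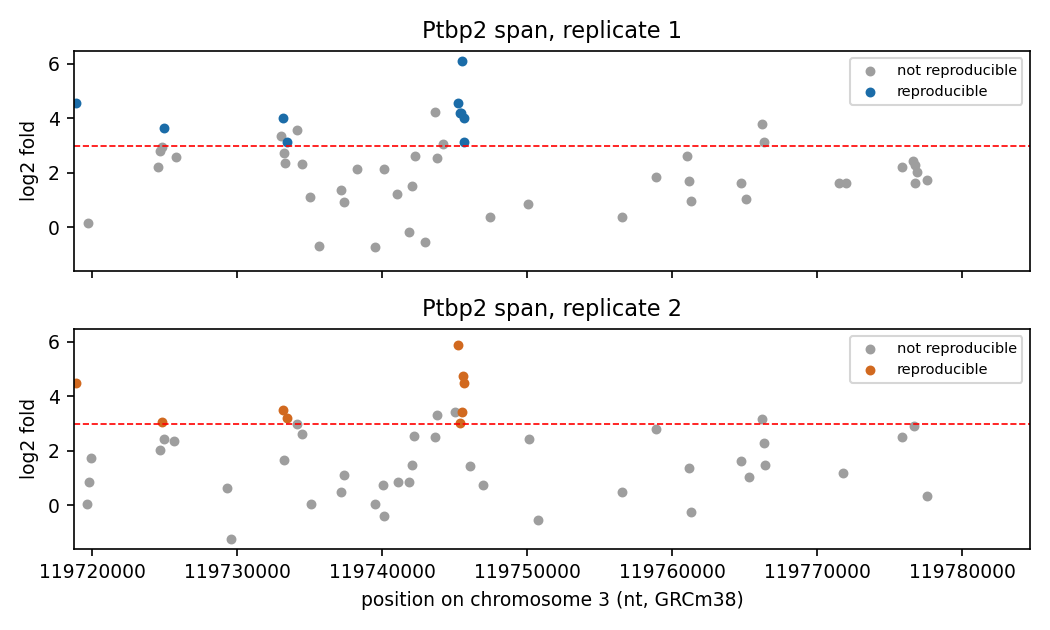
Log2 fold over input of each cluster in the Ptbp2 span against position on chromosome 3 (nt, GRCm38), one panel per replicate, with reproducible clusters in colour and others in grey. The red dashed line is the threshold of 3; the clusters of highest fold start at 119745474 in replicate 1 and at 119745169 in replicate 2.

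Genes of the actin cytoskeleton and the extracellular matrix were the lists with the largest excess of members with a reproducible cluster, but 0 of 20 lists passed the adjusted threshold. Of 36 actin cytoskeleton and myofibroblast genes, 27 had one against 19.8 ± 2.39 (SD) in matched random lists (permutation p = 0.0034, adjusted 0.068). Of 39 matrix genes, 24 had one against 18.1 ± 2.41 (permutation p = 0.023, adjusted 0.168). The PTB family and target list had 12 against 7.78 ± 1.76 (permutation p = 0.029, adjusted 0.168), fibroblast markers 6 of 12 against 2.83 ± 1.27 (permutation p = 0.0336, adjusted 0.168) and hnRNP genes 10 of 24 against 5.62 ± 1.87 (permutation p = 0.045, adjusted 0.18). These 5 lists had an unadjusted p under 0.05. With a log2 fold threshold of 1, 3 lists passed after adjustment (matrix, actin and fibroblast markers), and 8 had more members than chance by Fisher's exact test without matching.

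Several of the strongest sites within these lists lay in structural genes. Among matrix genes, Fbln2 (log2 folds of 6.07 and 6.39), the laminin gene Lamc1 (5.72 and 5.52), the collagen gene Col5a2 (5.75 and 5.37) and the elastin gene Eln (5.22 and 6.10) led. The pair in Lamc1 shared 3 nt and that in Eln 6 nt, so these folds are of neighbouring clusters. The actin list was led by Palld (5.41 and 5.31), the small GTPase gene Rhoa (5.70 and 5.19), the focal adhesion kinase gene Ptk2 (5.14 and 5.21) and Yap1 (4.99 and 5.67). Vim, which encodes vimentin, led the fibroblast markers with 7.34 and 5.12, ahead of Col3a1, Pdgfra and Gsn. In hnRNP genes the leading sites were in Hnrnpll, Hnrnpk, Hnrnpc and Pcbp2, where the folds of Hnrnpc were 5.57 and 4.21.

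The remaining lists were closer to their matched numbers, with permutation p from 0.0704 upward. Other splicing regulators had 14 of 27 members against 12.3 ± 2.13, led by Celf2, Mbnl1, Rbm5 and Rbfox1. TGF-beta signalling had 20 of 33 against 18.5 ± 2.36, led by Zeb2, Acvr2a, Acvr1 and Smad6. Sarcomere genes had 14 of 35 against 12.8 ± 2.23, and calcium handling and ion channel genes 17 of 33 against 18.7 ± 2.08, with Cacna2d1, Ryr2, Ank2 and Ank3 in the lead. Endothelial markers had 8 of 13 against 7.01 ± 1.54 (led by Flt1, Vwf, Ptprb and Cdh5), and pericyte and smooth muscle markers 6 of 10 against 3.21 ± 1.25 (Pdgfrb, Abcc9, Myh11 and Notch3). Macrophage markers had 4 of 11 against 3.04 ± 1.07, Schwann cell and neuron markers 4 of 9 against 3.50 ± 1.06, and cardiomyocyte markers 3 of 13 against 4.27 ± 1.31. SR protein genes had 2 of 14 against 2.11 ± 1.27 (Srsf11 and Tra2b), fatty acid oxidation genes 11 of 24 against 8.01 ± 1.92, oxidative phosphorylation genes 5 of 37 against 5.54 ± 2.01 and glycolysis genes 2 of 24 against 3.77 ± 1.61. None of 37 ribosomal protein genes and none of 6 erythroid markers had a reproducible cluster, against a mean of 1.26 and 0.126 in matched lists.

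**Figure D3:**
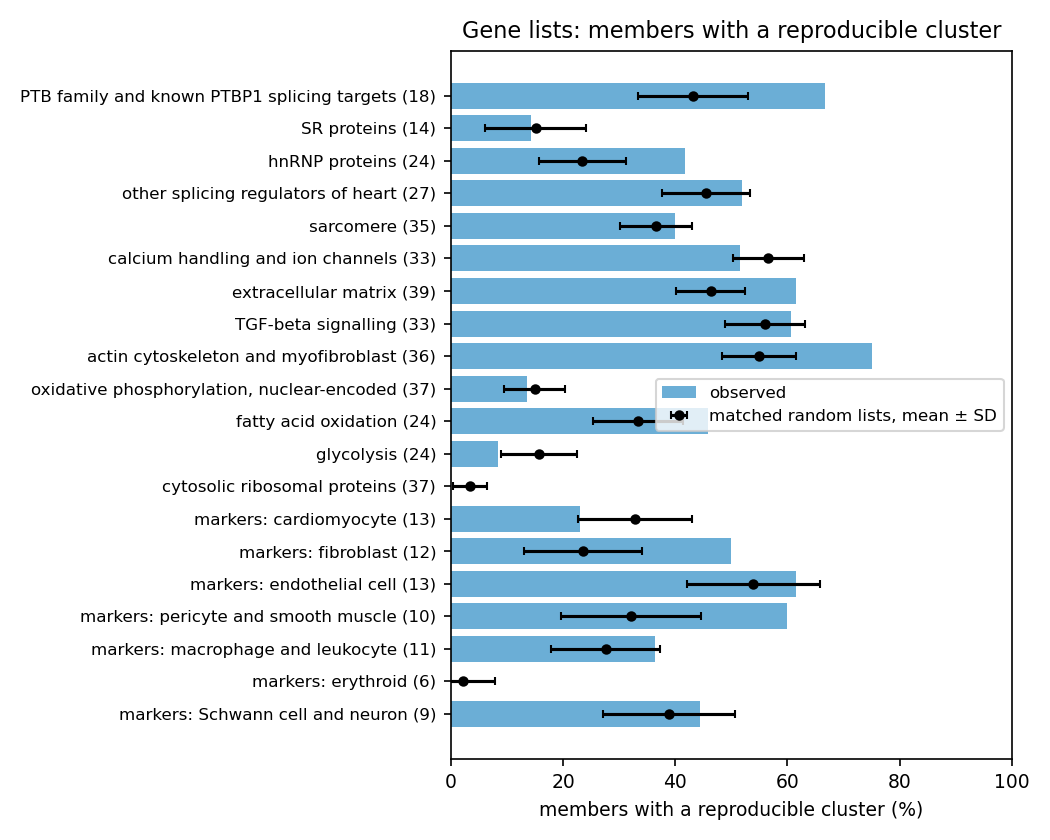
Percent of members of each gene list with a reproducible cluster (bars, number of members with clusters in brackets) and the mean ± SD of 10000 matched random lists (black points). The bar of the actin cytoskeleton list, 27 of 36 members, lies farthest to the right.

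Across all their clusters, genes of fibroblasts and the matrix had higher folds over input, and genes of cardiomyocytes and of abundant housekeeping functions had lower folds. The test behind this was chosen after seeing the data. Most folds lie on a ladder of whole steps (see Other observations), so how far gene medians follow coverage of the immunoprecipitate is unknown. For fibroblast markers, the mean of the gene medians was 1.48 ± 1.60 (SD over 12 genes) in replicate 1, which was 1.21 above matched genes, and 0.99 above in replicate 2 (permutation test, adjusted p = 0.0015 and 0.002). Matrix genes were 0.80 and 0.75 above (adjusted p = 0.000571 in both, from the smallest p these lists can give) and pericyte and smooth muscle markers 1.00 and 0.70 (permutation test, adjusted p = 0.00489 and 0.0392). The call of pericyte and smooth muscle markers ended when the mean fold per gene replaced the median (permutation test, adjusted p = 0.0664 in replicate 2). Of 39 matrix genes, 34 had a median above 0 in both replicates and 1 below. Members chosen after their values were seen were Vim with gene medians of 4.74 and 4.14, Bgn, the gene of the proteoglycan biglycan, with 5.24 and 4.13, and Col1a1 with 2.47 and 2.12.

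Ribosomal protein genes lay farthest below matched genes, with differences of −3.56 and −3.19 log2 units in replicates 1 and 2, and all 37 had medians below 0 in both replicates. The differences were −2.55 and −2.36 for 13 cardiomyocyte markers, −2.43 and −2.40 for 37 oxidative phosphorylation genes, −1.70 in both replicates for 35 sarcomere genes and −1.48 and −1.33 for 24 glycolysis genes. They were −0.72 and −0.64 for 33 calcium handling and ion channel genes. Each of these lists had an adjusted permutation p of 0.000571 in both replicates. Some lists share members, so their calls are not independent. The cardiomyocyte markers share Myh6 and Ttn, among others, with the sarcomere list and Ryr2 with the calcium list. Fibroblast markers share Col1a1 and Col3a1, among others, with the matrix list. Fatty acid oxidation genes were at −0.53 and −0.51 (adjusted permutation p = 0.012 and 0.0138). In the calcium and fatty acid lists the median member was slightly above 0 while the mean was below it. Gene medians, chosen after they were seen, were −4.21 and −3.62 in Myl2, −4.19 and −3.42 in Tnni3 and −3.60 and −3.12 in Ttn, against 0.52 and 0.41 in Myh6. The other 10 lists passed in neither direction. With random lists matched on the number of clusters and on span, 3 lists were higher and 7 lower; among genes with spans of at least 50000 nt only 13 of the 20 lists could be tested. Of these, sarcomere, calcium and cardiomyocyte genes stayed lower and matrix genes stayed higher, fatty acid oxidation and glycolysis lost their call, and endothelial markers gained a higher fold.

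**Figure D4:**
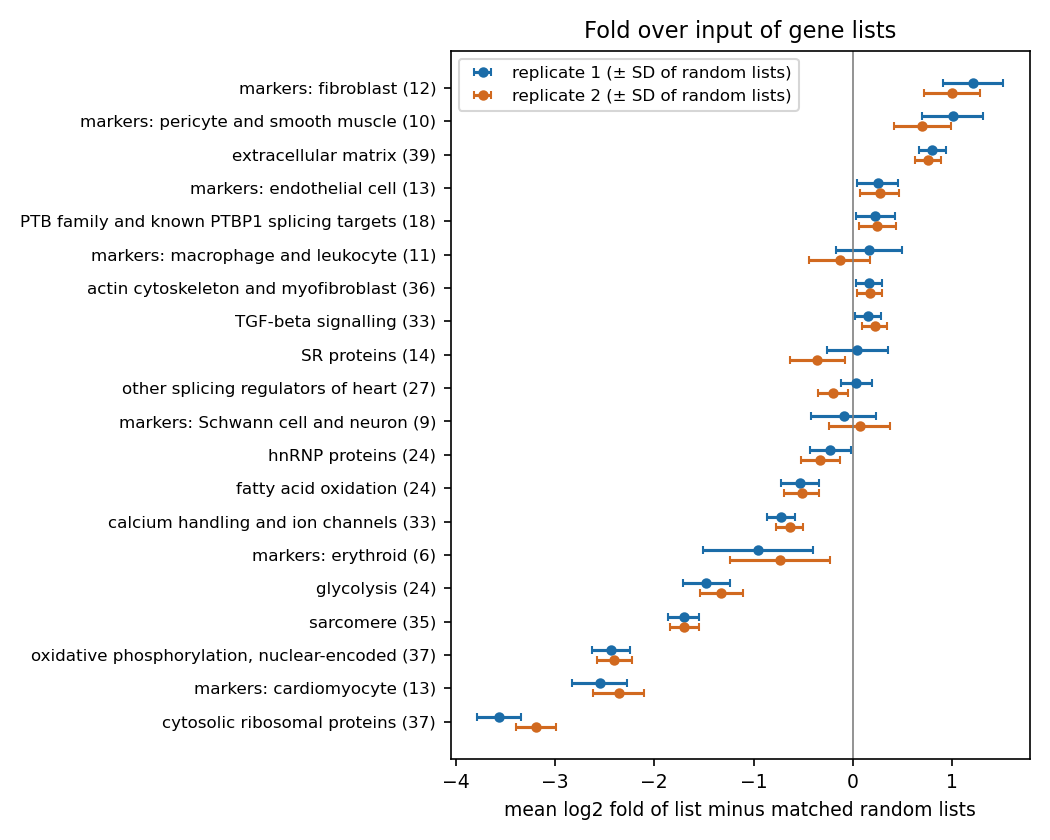
Mean over members of the gene median log2 fold, minus the mean of 10000 matched random lists, for each gene list (number of genes in brackets), with the SD of the random lists as error bars and replicates in blue and orange. Fibroblast markers lie at 1.21 and 0.99, ribosomal protein genes at −3.56 and −3.19.

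Enriched clusters were less frequent at the 3′ end of genes than other clusters. The tests of position and of gene class were chosen after seeing the data, in place of planned feature types. In replicate 1, 6.10% of enriched clusters lay in the last 10% of the gene span against 10.3% of the others (odds ratio 0.565, 95% interval 0.535 to 0.597). In replicate 2 it was 5.34% against 10.1% (odds ratio 0.499, 0.467 to 0.534). Fisher's exact test, adjusted over 4 tests, gave p = 1.71e-106 and 2.16e-113. The share in lncRNA genes was 1.42% of enriched clusters against 2.09% of the others in replicate 1 and 1.42% against 2.05% in replicate 2 (odds ratios 0.673 and 0.691; Fisher's exact test, adjusted p = 2.98e-13 and 2.43e-09). Protein-coding genes held 96.2% against 95.6%, and 96.1% against 95.7% (Fisher's exact test, adjusted p = 1.56e-05 and 0.00547). Outside gene spans lay 2.05% against 1.70%, and 2.20% against 1.66% (odds ratios 1.21 and 1.34, Fisher's exact test, adjusted p = 9.75e-05 and 1.03e-07). Of the 486 and 404 enriched clusters there, 208 and 202 were in 1 region of chromosome 7. Without that region, the share of enriched clusters outside gene spans was below that of the others in both replicates. The excess outside gene spans thus came from that region alone. Clusters are not independent of each other, since many touch, so these p-values are too small. Exons, introns and untranslated regions were not separated here.

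**Figure D5:**
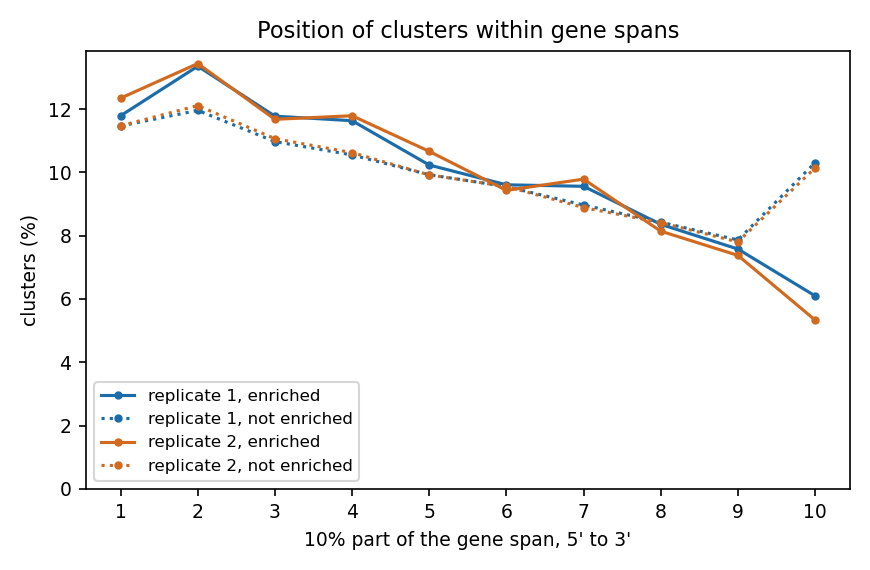
Percent of clusters in each 10% of the gene span from 5′ to 3′, for enriched (solid) and not enriched (dotted) clusters of each replicate. In the last 10%, enriched clusters lie at 6.10% and 5.34%, and the others lie at 10.3% and 10.1%.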

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

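All tests of explanations in this part were chosen after the results were seen. Outside all protein-coding and lncRNA gene spans lay 372 reproducible clusters, a signal the gene comparisons did not use, of which 208 were in 1 region of chromosome 7 from 44473836 to 44483121, on the + strand. That region, between Josd2 and 5430431A17Rik, held more reproducible clusters than any gene. All of its 208 clusters in replicate 1 and all 202 in replicate 2 were enriched, with median log2 folds of 5.28 and 4.62 among the shared ones. These clusters were short, covering 5188 nt in replicate 1 and 5185 nt in replicate 2 of the 9286 nt region. Their number is therefore not a count of separate sites. On the mitochondrial genome 1 cluster was reproducible, from 11751 to 11817, with log2 folds of 4.21 and 3.99, among 161 mitochondrial clusters in replicate 1 and 181 in replicate 2.

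The first pattern weighed is the higher fold over input of genes of the matrix and of several non-myocyte cell types than of cardiomyocyte genes. The mean of gene medians was 1.16 in 79 genes of the matrix and of fibroblast, endothelial, mural and macrophage markers, and −0.76 in 71 sarcomere, calcium and cardiomyocyte genes, a difference of 1.92 in replicate 1 and 1.76 in replicate 2. These lists were put together after their folds were seen, so no p-value is given for the difference and the comparisons below only describe it. Erythroid markers, left out of them, went the other way with means of −1.10 and −0.98, and Schwann cell and neuron markers, also left out, had 0.32 and 0.40. With both added, the difference was 1.70 in replicate 1 and 1.59 in replicate 2. Matching on the number of clusters and the span of the genes did not reduce the difference. Against random lists matched on both, it was 1.95 ± 0.17 (SD of random lists) in replicate 1 and 1.79 ± 0.16 in replicate 2. The matching was coarse, with 10 bins of cluster number and 5 bins of span, so a part played by span is not excluded. Abundant spliced RNA of cardiomyocytes in the input may account for part, since among genes with spans of at least 100000 nt the difference was 0.83 ± 0.24 (SE) in replicate 1 and 0.81 ± 0.21 in replicate 2, smaller than over all spans but above 0; spliced and unspliced RNA cannot be told apart without exons. No group of the design separates cell types, so no biological explanation was tested, and a difference in PTBP1 level between cell types stays open.

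The second pattern is the larger number of enriched clusters in replicate 1, 23757 against 18330. The constants of the fold scale (see Other observations) differed by 0.0028 log2 units with every candidate step. Cluster pairs enriched in both replicates differed by a median of 0.30. These values argue against the scaling of immunoprecipitate over input only if the constant holds that scaling, which was not tested. A deeper immunoprecipitate in replicate 1 could contribute. Over 81152 overlapping clusters enriched in neither replicate, the summed steps of the fold scale in replicate 1 were 1.06 times those of replicate 2. That is too close to 1 to decide, and whether steps measure depth was not tested. Library depth and a difference in pull-down cannot be told apart without read counts, and no biological explanation was tested.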

How the results depend on the processing

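The tests of position and gene class, the fold tests of gene lists and their alternatives, the adjusted deposited p, joined clusters, the last 2000 nt, pairing by most shared nucleotides and the cell-type difference were chosen after seeing the data. At a log2 fold threshold of 1, replicate 2 had 29012 enriched clusters and 25554 clusters were reproducible, and at a threshold of 2, 23937 were, because the looser threshold admits more clusters. Replicates taken alone gave 18330 to 23757 clusters in place of 14958. Replicate correlation was 0.228 over pairs enriched in at least 1 replicate and 0.570 over pairs with a −log10 p of at least 3 in both; narrowing the range of folds lowers it by construction. Lists with more members than matched lists numbered 0 in the main setting, 3 at a fold threshold of 1, 1 at 2, 2 at a −log10 p of 5, 1 at reciprocal overlap of 50%, 0 to 2 with replicates taken alone, and 8 with Fisher's exact test without matching, which ignores gene size; that test also gave 1 list with fewer. The actin list passed in 5 of these settings. Calcium handling and ion channels went from −1.67 members against matched lists to 8.77 above without matching. Lists with higher fold numbered 5 without matching in place of 3, with TGF-beta signalling and actin genes added; calcium handling and fatty acid oxidation then lost their lower fold and erythroid markers gained one. Lists with lower fold numbered 3 among genes with spans of at least 50000 nt in place of 7, where only 13 lists could be tested. Fatty acid oxidation lost its call there and endothelial markers gained a higher fold; glycolysis, with 3 such genes, then had a difference of 0.098 (permutation test, adjusted p = 0.83). The cell-type difference of 1.92 and 1.76 was 1.70 and 1.59 with erythroid and Schwann cell and neuron markers added. Averaging folds per gene ended the call of pericyte markers (permutation test, adjusted p = 0.0664 in replicate 2). The cause was not tested. Other counts of clusters and genes stayed within 1.5 times, and the deficit at the 3′ end kept its sign in the alternatives tried, from −5.77 to −1.94 percentage points. Ndufs1, Ndufa9, Ncam1 and Scn7a lost their reproducible cluster at a −log10 p of 5, Gsn lost it at reciprocal overlap of 50%, and Tpm1 gained one at lower fold thresholds. No paired analysis was possible because each deposited value already sets an immunoprecipitate against its own input. Alternatives that need read counts, exons or sequence were not run.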

Other observations

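Tests in this part were chosen after seeing the data, and the genes in it were chosen after their values were seen. Counted per length of gene, among genes with at least 5 reproducible clusters, the one with most was Xist, the noncoding RNA that silences an X chromosome, with 47 reproducible clusters, or 20.6 per 10 kb of its 22861 nt span, and gene medians of 5.38 and 4.11 on the log2 scale. Bgn, the biglycan gene, followed with 19 clusters or 15.4 per 10 kb, then Gpr4, a proton-sensing receptor gene, with 14. Dbp, the gene of a circadian transcription factor, had 5 or 9.80 per 10 kb, and the protease gene Htra3 24 or 8.64 per 10 kb. Myl3 stood apart from other sarcomere genes, with 5 clusters or 8.16 per 10 kb and gene medians of 2.72 and 2.57.

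Among metabolic genes, Pdk4, which inhibits pyruvate dehydrogenase, had gene medians of 4.14 and 3.19 and 5 reproducible clusters, and the fatty acid transporter gene Cd36 had 2.48 and 1.77 and 11 clusters, while the medians of Hadha were −3.25 and −3.37. The strongest reproducible clusters of Pdk4 and Cd36 reached the cap of 400 on the −log10 p scale in both replicates in the authors' deposited tables, as did those of Myh6 and Ttn.

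Most deposited folds lie on a ladder. The step was chosen among 8 candidates in each replicate, as the one with most whole multiples among those that did not leave the odd multiples rare, a limit set after a finer step had been picked without it. In replicate 1, 67.2% of clusters had a fold that was a whole multiple of 1 step within 0.005, and in replicate 2 it was 64.4%. Among enriched clusters the shares were 67.5% and 61.7%. With this step, the log2 fold threshold of 3 was first reached at 32 steps in both replicates. Gene medians could lie on the ladder as well. In replicate 1 the median over all 13538 genes, 0.36, was a whole multiple of the step, and Palld, Cacna2d1 and Hk1 had the same gene median. What a step stands for was not tested, so how far folds and gene medians follow coverage of the immunoprecipitate is unknown. The fold results of gene lists share this limit. The finer step made 79.8% and 77.8% whole, but odd multiples were then 0.186 and 0.205 times as many as even ones, while the step used had more odd than even multiples. Of clusters with a −log10 p of at least 3, 28.4% in replicate 1 and 37.1% in replicate 2 fell below the fold threshold.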
